A study of Mus musculus with 4 samples.

How the data were processed

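Total RNA was isolated from synovium with the mirVana kit and 500 ng per sample were reverse transcribed with a TaqMan microRNA kit, per the labels' protocols. The deposited values are raw Ct values from a BioMark system, per the file headers, with 999 for wells without amplification, which is read from the values. The thresholds and quality settings behind the Ct values are not given in the sources used here. Ct values ran from 2.50 to 26.997, and 2083 of 6096 wells had one. The authors also deposited a table of group averages and differences on a log2 scale and of the fold (ratio) between the groups, and how it was normalized is not given in the sources used here. Its values were used only for comparison.

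The 4 pools were grouped by their labels into 2 non-arthritic and 2 arthritic pools, which the labels call biological replicates. The wells of a pool are not numbered in the files and were averaged where both had a Ct, and a pool counted as detected where at least 1 well had a Ct under 35. Assays detected in all 4 pools entered the test, 134 on panel A and 75 on panel B. The level of an assay was the median Ct of these miRNA assays in the same pool and panel minus its Ct, which takes 1 cycle as a doubling. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no pairing of pool numbers) with Benjamini-Hochberg adjustment at 0.05. The prior had 4.02 degrees of freedom and an SD of 0.874, beside 2 residual degrees of freedom. An exact permutation test of a single miRNA could not go below p = 0.333 with 2 pools per group, so the calls rest on limma's sharing of spread across assays. Control assays were left out of the fit, which the design had not spelled out. A fit with them kept in the moderation, run earlier, gave 42 changed miRNAs against 45.

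The 21 miRNA lists and the rule for named miRNAs were written before the data were examined. The rule took the 12 largest rises and 12 largest falls among the miRNAs that passed with both arthritic pools outside the non-arthritic range, 17 miRNAs named whatever their values, the control RNAs, 2 to 4 members of each list with the smallest p, and up to 6 miRNAs per direction detected in 1 group only. Lists with at least 3 members detected in all 4 pools, 13 in number, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The other 8 lists are described by their members. A member was matched to the mouse-named assay, and where there was none to the human-named assay, a rule added after the assay names were seen. Bounds for miRNAs detected in 1 group only use the highest recorded Ct, 26.997, in place of the limit of 35 in the plan, because no Ct lay above it and a limit of 35 would enlarge the folds.

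The fit was tested on simulated data for this comparison with 209 assays, 20 of them changed at each size in 50 runs. It recovered 10.8% of changes of 2 log2 units, 64.4% of changes of 4 and 91.3% of changes of 6, and 4.26% of its calls were unchanged assays, so that changes under about 4 log2 units were often missed. camera called 6 of 650 lists there. The simulated spreads were drawn from limma's own fitted prior, alike in both groups and independent between assays, with no pool or chip effects. The low shares of false calls were thus largely built in. They do not give the error rate in the real pools, where the arthritic pools differed more than the non-arthritic. Precision was limited by the 2 pools per group: the median standard error of a log2 change was 0.87, the arthritic pools differed by a median of 1.38 log2 units per assay and the non-arthritic pools by 0.52. The duplicate SD was 0.730 cycles for Ct under 10 and 1.23 cycles for Ct from 20 to 24. In arthritic pool 2 on chip A3 the second listed well gave a Ct for 24 assays and the other for 36.

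The alternatives were other normalizations, Ct limits, detection filters, treatments of wells, moderation, thresholds, a block for the pool number, and each pool left out. The median per chip, Ct limits of 24 and 26, the control assays in the moderation, undetected values at the highest Ct and leaving out the second listed well on chip A3 were chosen after seeing the data. Neighbouring miRNA genes were found by symbol in a RefSeq gene table of assembly GRCm38.p6, which matched 135 of 160 mouse-named assays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.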

Results

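The abundance of microRNAs (miRNAs), short RNAs that repress messenger RNAs, was measured by TaqMan real-time PCR on nanolitre chips in mouse synovium, the tissue that lines joints. The tissue came from around the ankle (tibiotalar) joint of C57BL/6J mice. In the K/BxN serum transfer model, serum from arthritic K/BxN mice brings on joint inflammation in the recipients. 2 pools of non-arthritic synovium were taken at day 0, each from 3 mice, and 2 pools of arthritic synovium at day 10, at the peak of inflammation, each from 10 mice. Every pool was read in 2 technical wells with 750 miRNA assays and 12 control positions on 8 chips, which form panels A and B. An assay's Ct is the cycle at which its signal crosses a threshold, so that 1 cycle less stands for about 2 times as much RNA, assuming doubling per cycle. Of the 750 miRNA assays, 294 and 287 gave a Ct in non-arthritic pools 1 and 2, and 271 and 223 in arthritic pools 1 and 2. The median Ct of the panel A assays detected in all 4 pools was 12.6 and 12.8 in the non-arthritic pools, 12.5 in arthritic pool 1 and 15.9 in arthritic pool 2. The SD between duplicate wells was 0.883 and 1.04 cycles in the non-arthritic pools and 0.761 and 1.47 cycles in arthritic pools 1 and 2. Levels below are the pool's median Ct in the panel minus the assay's Ct, in log2 units, and they were compared over the 209 assays detected in all 4 pools.

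The comparison asked which miRNAs differ between arthritic and non-arthritic synovium. Of the 209 assays, 45 passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), of which 20 rose and 25 fell in the arthritic pools. The largest rise was that of miR-296-5p, described in endothelial cells. Its level went from -12.4 ± 0.26 in the non-arthritic to -4.53 ± 0.47 in the arthritic pools (SD, n = 2 pools each). The difference was 7.85 ± 0.75 log2 units (SE) or 231-fold (limma adjusted p = 0.00421). The non-arthritic level stands for a Ct near the highest recorded, so that the size of this rise is uncertain. Duplicate wells had an SD of 1.15 cycles for Ct from 24 to 27. The assay was tested in 20 of 22 alternative settings, where its lowest log2 change was 5.00. miR-135a rose by 7.30 ± 0.80 log2 units, 158-fold, from -10.7 ± 0.36 to -3.37 ± 0.78 (SD, n = 2 pools each, limma adjusted p = 0.00421). let-7f, of the let-7 family of miRNAs that restrain growth and dedifferentiation, rose by 6.66 ± 0.99 log2 units (SE, limma adjusted p = 0.0122). The growth-promoting miRNAs miR-106b, miR-19a and miR-20a, of the miR-17-92 cluster and its paralogs, rose by 5.73 ± 0.97, 4.98 ± 1.01 and 4.05 ± 0.75 log2 units (SE). miR-34c, a transcriptional target of p53, rose by 4.75 ± 1.06, and the human-named assay of miR-671-5p by 5.78 ± 0.93. miR-652, miR-467a (the panel A assay), miR-28 and miR-329 rose by 5.13 ± 1.12, 4.71 ± 0.73, 4.01 ± 0.81 and 3.94 ± 0.91 log2 units.

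miR-184 fell with a log2 change of -11.8 ± 2.38 (SE, limma adjusted p = 0.0235), the largest fall over all pools, and its arthritic pools lay far apart, at -14.2 and -6.57. The level of -14.2, in arthritic pool 1, stands for a Ct close to the highest recorded, 26.997, so that the size of this fall is uncertain. Without arthritic pool 1 the log2 change of miR-184 was -7.93, behind miR-222 at -8.80. miR-222, encoded next to miR-221, went from 2.65 ± 0.14 to -5.37 ± 1.16 (SD, n = 2 pools each), a log2 change of -8.02 ± 0.86 (SE, limma adjusted p = 0.00421). miR-133a, a miRNA of skeletal and heart muscle, went from 8.33 ± 0.56 to 1.26 ± 0.54, a log2 change of -7.07 ± 0.78. Without the second listed well of arthritic pool 2 on chip A3 the log2 change of miR-133a was -5.74. miR-186 and the human-named assay of miR-30a-3p had log2 changes of -7.26 ± 0.74 and -7.03 ± 1.25. miR-16, which restrains the cell cycle, went from 5.36 ± 0.15 to -1.07 ± 1.64, a log2 change of -6.43 ± 0.98. It was also read on chip A3. Without the second listed well there, the log2 changes of miR-15a and miR-16 differed by 2.19, against 4.11 with it. miR-204, which limits the osteoblast factor Runx2, had a log2 change of -5.74 ± 0.86, and miR-339-3p one of -6.26 ± 0.92. The human-named assay of miR-421, miR-384-5p, miR-30e and the human-named assay of miR-29a* had log2 changes of -5.42 ± 1.07, -5.32 ± 0.74, -4.94 ± 0.78 and -4.78 ± 1.31 (SE). The last was -3.10 without arthritic pool 2.

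**Figure D1:**
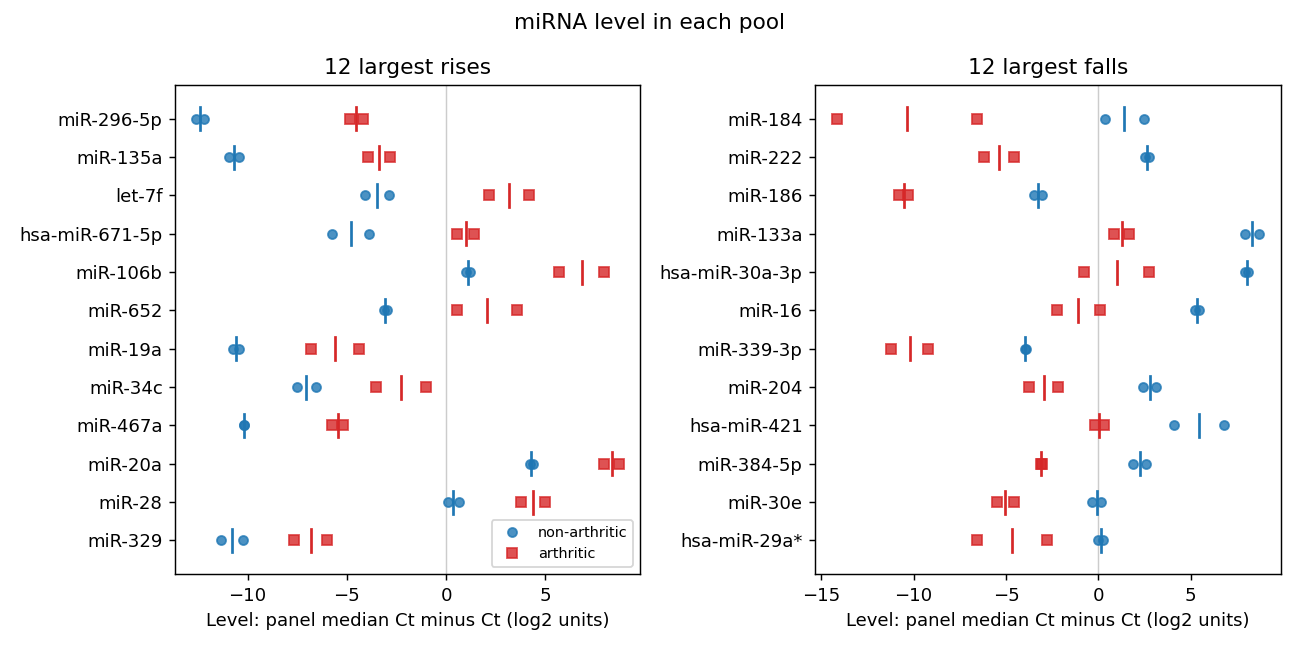
Level of each of the 12 miRNAs with the largest rise (left) and fall (right), as the panel median Ct minus the Ct in log2 units, with circles for the 2 non-arthritic pools, squares for the 2 arthritic pools and vertical bars for group means. The 2 groups do not overlap for any of the 24, and miR-184 has the widest gap between arthritic pools, at -14.2 and -6.57.

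The 45 changed miRNAs all had both arthritic pools above, or both below, the 2 non-arthritic pools. So did 71.3% of the 209 tested, against the 33.3% that chance gives for 1 assay with 2 pools per group, and assays of the same pools are not independent. None of the 45 changed sign under any of the 8 other normalizations tried, but the counts depended on the normalization. With U6 alone as the reference 1 rose and 54 fell, with U6, snoRNA135 and snoRNA202 together 3 rose and 47 fell, and with the 2 snoRNAs 4 rose and 54 fell. With raw Ct 0 rose and 8 fell (65 miRNAs at an unadjusted p under 0.05), and with the panel mean 12 rose and 13 fell. miR-222, miR-186, miR-133a, miR-339-3p and miR-204 passed, lower in the arthritic pools, under all 8. Of the rises, miR-142-3p, miR-329 and miR-19a passed under 1 of the 8, miR-34c, miR-18a, miR-485-3p and miR-1949 under 2, and miR-2135 under 0. miR-296-5p passed under 7, miR-135a under 6, let-7f and miR-671-5p under 5, miR-28 and miR-467a under 4 and miR-652 under 3. Among the falls the fewest was 3, for miR-136, miR-143, miR-1982.2 and miR-138. By limma the count was 0 without non-arthritic pool 1 or 2, where 42 and 25 miRNAs had an unadjusted p under 0.05. It was 121 without arthritic pool 1 and 97 without arthritic pool 2. Ordinary linear models in place of limma's moderation gave 0 (55 at an unadjusted p under 0.05).

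miR-146a and miR-146b, which NF-kappaB induces and which damp inflammatory signalling, fell along with miR-222 in the list of inflammation-responsive miRNAs. miR-146a went from 7.36 ± 0.44 to 3.06 ± 0.74 (SD, n = 2 pools each), a log2 change of -4.30 ± 0.79 (SE, limma adjusted p = 0.0200), and miR-146b had a log2 change of -4.08 ± 0.80 (SE). A rat-named assay of miR-146b had a log2 change of -1.61 ± 0.83 and did not pass (limma adjusted p = 0.177). Of the 11 members tested, 0 rose, 3 fell and 8 did not pass, and 6 passed when adjusted over the list alone, 3 higher and 3 lower. The 3 higher were miR-21, miR-221 and miR-125b-5p. miR-21, a miRNA raised in many inflamed tissues, had a log2 change of 2.95 ± 0.89 (limma adjusted p = 0.0651), miR-221 one of 2.25 ± 0.77 and miR-125b-5p one of 2.91 ± 1.00 (limma adjusted p = 0.0814 for both), so that none of these passed over all assays. miR-203 had a log2 change of 0.87 ± 0.74. The values of miR-221 and miR-203 were below 0 with each of the 3 control-RNA references, that of miR-203 also with raw Ct. For miR-21 the lowest log2 change among the alternatives was 0.095. Its Ct was 12.4 and 12.9 in the non-arthritic pools, 8.63 in arthritic pool 1 and 13.8 in arthritic pool 2. miR-155, induced in activated immune cells, gave a Ct in both wells of arthritic pool 1 (mean 21.6), in 1 well of non-arthritic pool 1 (26.965) and in no well of the other 2 pools, and was not tested.

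Among myeloid miRNAs, miR-142-3p, found across blood cells, rose by 3.83 ± 0.97 log2 units (SE, limma adjusted p = 0.0402), a call that was lost under 7 of the 8 other normalizations. Without the second listed well of arthritic pool 2 on chip A3, a chip that does not hold its assay, the log2 change was 3.56 (limma adjusted p = 0.0796). miR-223, of neutrophils and other myeloid cells, had a log2 change of 1.77 ± 0.85 (limma adjusted p = 0.150), below 0 with the 3 control-RNA references. Of the 2 myeloid members tested 1 rose, as it did when adjusted over the list alone, and another member, miR-511, was detected only in the non-arthritic pools. Of the 6 lymphoid and broad haematopoietic members tested 0 passed, also when adjusted over the list alone. miR-150, of mature lymphocytes, had a log2 change of -1.99 ± 0.79, miR-181a one of 2.43 ± 0.75 that was below 0 with the 3 control-RNA references, and miR-29a one of -1.99 ± 0.79. The erythroid miR-451 had a log2 change of -0.78 ± 0.87 and did not pass, with 0.54 without arthritic pool 2 and 0.072 with the median per chip.

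Among the skeletal and heart muscle miRNAs miR-133a fell, and miR-1 and miR-133b gave a Ct in both non-arthritic pools and in no arthritic well. The human-named assay of miR-206 had a log2 change of -2.41 ± 0.87 (SE, limma adjusted p = 0.0931), from -2.99 to -1.48 without 1 pool, and did not pass. When adjusted over the list alone, 2 of the 2 muscle members tested passed. In the list of smooth muscle and pericyte miRNAs, miR-143 had a log2 change of -4.12 ± 1.00 (SE, limma adjusted p = 0.0373) and fell, while miR-145 had one of -2.09 ± 0.87, from -2.41 to -1.20 without 1 pool, and did not pass, and 1 of 2 passed when adjusted over the list alone. miR-143 was at -2.43 without arthritic pool 2, and a human-named assay of it had a log2 change of -2.06 ± 0.75 and did not pass. In the endothelial list miR-296-5p rose, while miR-126-3p and miR-126-5p had log2 changes of -2.38 ± 0.74 and -2.02 ± 1.03 and did not pass (1 of 3 rose, 2 of 3 passed when adjusted over the list alone, 1 higher and 1 lower). The cartilage miRNAs miR-140 and miR-455 had log2 changes of -1.78 ± 0.90 and 1.93 ± 0.76, the latter below 0 with the 3 control-RNA references, and 0 of 2 passed either way. Of the 6 adipose members tested 0 passed, with log2 changes of -5.005 ± 2.24 for the human-named assay of miR-196a, -2.24 ± 1.25 for miR-193b and -2.13 ± 1.39 for miR-365. Without 1 pool these ran from -8.66 to -1.57, from -3.48 to -0.42 and from -3.67 to -0.014. Of the 3 epithelial members tested 0 passed, with -2.09 ± 0.79 for miR-182 and -0.97 ± 1.03 for miR-205, which was 0.14 without arthritic pool 1. The hypoxia-responsive miR-210 had a log2 change of -1.79 ± 1.19 and the liver miR-192 one of 0.22 ± 0.77, below 0 with the control-RNA references and raw Ct, and neither passed. Without 1 pool miR-210 ran from -2.89 to -0.10, miR-140 from -2.67 to -0.31 and miR-126-5p from -3.20 to -0.26. Of the neural list 0 members were detected in all 4 pools.

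Of the 10 members of the miR-17-92 cluster and its paralogs tested, 4 rose (miR-106b, miR-20a, miR-19a and miR-18a, the last by 3.17 ± 0.74 log2 units, SE), 0 fell and 6 did not pass, and 5, all higher, passed when adjusted over the list alone. Under the 8 other normalizations miR-106b and miR-20a each passed in 4, miR-18a in 2 and miR-19a in 1. miR-19a, measured on chip A4, had a log2 change of 4.71 without the second listed well of arthritic pool 2 on chip A3 (limma adjusted p = 0.0520). Of the 65 assays of the Dlk1-Dio3 cluster, an imprinted locus with many miRNA genes, 40 gave no Ct in any pool and 13 were tested, of which 3 rose, 1 fell and 9 did not pass (6 passed when adjusted over the list alone, 4 higher and 2 lower). The log2 changes were 3.94 ± 0.91 for miR-329, 3.61 ± 0.81 for miR-127, 2.73 ± 0.72 for miR-485-3p and -4.70 ± 1.28 for miR-136, the last from -6.48 to -2.35 without 1 pool. miR-136 passed under 3 of the 8 other normalizations. It did not pass without the second listed well of arthritic pool 2 on chip A3 (limma adjusted p = 0.0795). Of the 21 assays listed from osteoblast and osteoclast studies 18 were tested, of which 3 rose, 4 fell and 11 did not pass (8 passed when adjusted over the list alone, 4 higher and 4 lower). Those that rose were miR-135a, miR-34c and miR-29b, and those that fell were miR-222, miR-133a, miR-204 and miR-138. The call of miR-138 was lost without the same well on chip A3 (limma adjusted p = 0.0520). In the miR-29 family, which targets collagen messenger RNAs, miR-29b rose by 2.90 ± 0.77 log2 units (SE, limma adjusted p = 0.0466). It passed under 3 of the 8 other normalizations, and its lowest log2 change among the alternatives was 0.045. miR-29a and miR-29c, the latter at 0.80 ± 0.76 and below 0 with the control-RNA references and raw Ct, did not pass (1 of 3 passed when adjusted over the list alone). let-7f was the 1 of 7 let-7 members tested that rose, also when adjusted over the list alone. let-7e and let-7i had log2 changes of 1.78 ± 0.75 and 1.72 ± 0.75, below 0 with the 3 control-RNA references. In the miR-15/16 family miR-16 fell, and miR-15b and miR-15a had log2 changes of 3.25 ± 0.92 and -2.32 ± 0.74 and did not pass (1 of 5 fell, 3 of 5 passed when adjusted over the list alone, 1 higher and 2 lower). In the miR-30 family miR-30e was the 1 of 5 members tested that fell, also when adjusted over the list alone. miR-30d had a log2 change of -1.67 ± 0.74, which was 0.021 without the second listed well of arthritic pool 2 on chip A3. miR-30b had one of 0.88 ± 0.72, below 0 with the control-RNA references and raw Ct. Of the 10 assays of the fibroblast and mesenchymal list 8 were tested and 0 passed either way, with 2.35 ± 1.07 for miR-10a, 2.32 ± 0.85 for miR-214 and 1.68 ± 0.92 for miR-199b. Each was below 0 with U6 alone, the first 2 also with the other control-RNA references and miR-199b with raw Ct. Without 1 pool miR-10a ran from 1.56 to 3.72 and miR-199b from 0.72 to 2.43.

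**Figure D2:**
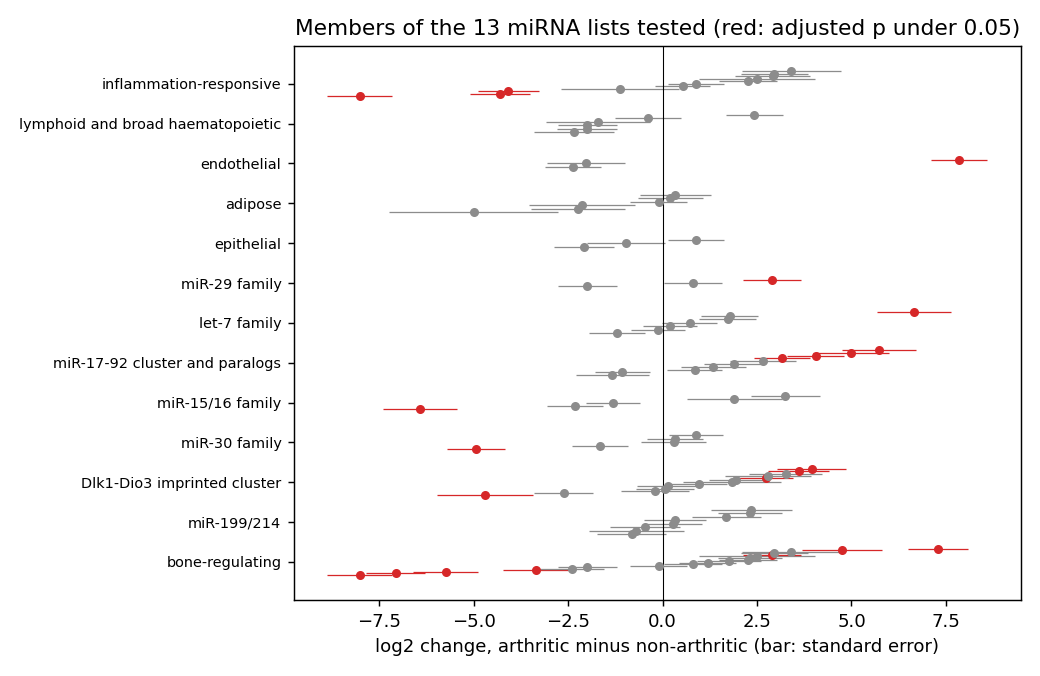
Log2 change, arthritic minus non-arthritic, of each member of the 13 lists with at least 3 members detected in all 4 pools, with the standard error as a bar and red for members with an adjusted p under 0.05. Of the 10 tested members of the miR-17-92 cluster and paralogs 4 are red, all above 0, and of the 11 inflammation-responsive members 3 are red, all below 0.

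As groups, 0 of the 13 lists passed limma's camera test with a preset correlation of 0.01 after Benjamini-Hochberg adjustment, and 1, the miR-17-92 list, had an unadjusted p under 0.05 (camera p = 0.0117, adjusted p = 0.153, adjusted p = 0.868 with an estimated correlation). With fry 4 lists had an unadjusted p under 0.05, and the smallest adjusted p was 0.0958. Of the alternatives run, the miR-17-92 list passed camera without arthritic pool 2 and with undetected values at the Ct limit. Its median log2 change was 2.27, and it was -0.58 with U6 alone. All 8 lists with a median above 0 had a median below 0 with each of the 3 control-RNA references. The median, the mean and the directions of the 2 tests differed in sign in 3 lists. In the inflammation-responsive list the median was 0.87, the mean -0.19, camera's direction up and fry's down. In the endothelial list the median was -2.02, the mean 1.15, camera's direction down and fry's up, and without 1 pool the median ran from -2.42 to -0.26. In the miR-30 family the median was 0.29, the mean -1.02 and both directions down.

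Of the assays outside the test, 27 gave a Ct in both non-arthritic pools and in no arthritic well, and 4 in both arthritic pools and in no non-arthritic well. Arthritic pool 2 gave the fewest Cts, for 223 assays against 294 and 287 in the non-arthritic pools. The counts of 27 and 4 therefore depend on detection as well. Bounds set the other group at the highest recorded Ct, 26.997, and hold only if a well without a Ct lay beyond it. Wells could also fail well inside the range. miR-1897-3p had non-arthritic Cts of 17.4 and 13.7, yet a Ct in only 3 wells. On chip A3 the 2 wells of arthritic pool 2 gave a Ct for 36 and 24 assays. The bounds below are therefore conditional. Among the 27 the smallest bound was -0.64, for the rat-named assay of miR-29c*, which does not show it to be lower. miR-486, abundant in red cells and muscle, was lower in the arthritic pools by at least 11.26 log2 units, miR-194, of liver and gut, by at least 10.67, and miR-1897-3p by at least 9.59. miR-511, of macrophages and dendritic cells, was lower by at least 8.79 log2 units, miR-672 by at least 8.52 and miR-23a by at least 7.21. miR-1 and miR-133b were lower by at least 6.27 and 3.83 log2 units. The 4 detected only in the arthritic pools were higher there relative to the panel median. The bound was 6.41 log2 units (84.8-fold) for let-7a, 4.38 for the rat-named assay of miR-351, 3.97 for miR-467c and 3.57 for miR-130b. No bound was computed with another reference. U6 on panel A, which holds these 4 assays, was itself higher relative to that median by 2.86 log2 units. With U6 as the reference their bounds would therefore be smaller. Of the miRNAs detected in 1 group only, miR-486 is in the erythroid, miR-511 in the myeloid, miR-194 in the liver and miR-23a in the fibroblast and mesenchymal list, and let-7a in the let-7 family. let-7a had a Ct of 17.7 in arthritic pool 1 and 26.4 in arthritic pool 2. From 1 pool alone the bound was 3.73 or 9.08 for let-7a, 1.68 or 7.08 for the rat-named assay of miR-351 and 3.92 or 8.63 for miR-1. For miR-1897-3p, which had a Ct in 3 non-arthritic wells, it was 7.64 or 11.53.

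The control RNAs did not follow the miRNA assays. The small nuclear RNA U6 came up at a Ct of 7.61 and 6.56 in the non-arthritic and 5.78 and 5.67 in the arthritic pools on panel A. On panel B it came up at 5.55, 4.59, 4.87 and 5.07, while the median miRNA Ct there was 15.5, 15.6, 16.5 and 18.4. Relative to the panel median U6 was therefore higher in the arthritic pools, by 2.86 log2 units on panel A and 1.97 on panel B. Arthritic pool 2 gave much of this. On panel A arthritic pools 1 and 2 were at 6.76 and 10.2 against a non-arthritic mean of 5.64. On panel B they were at 11.6 and 13.4 against 10.5. With raw Ct the differences were -1.36 and -0.10 cycles, arthritic minus non-arthritic. snoRNA135 had differences of 4.61 and 2.03 log2 units and snoRNA202 of 0.76 and -0.77. snoRNA202 thus had opposite signs on the panels, but on panel A the sign rests on arthritic pool 2. Its levels there were 3.13 and 6.45 in arthritic pools 1 and 2, on either side of the non-arthritic mean of 4.03. With raw Ct snoRNA202 came up later in the arthritic pools on both panels, by 0.735 and 2.64 cycles. Taking U6 alone as the reference moved the median change of the 209 assays by -2.70 log2 units, the 2 snoRNAs by -2.09 and all 3 by -2.36, so that changes given here are relative to the median miRNA. U87, Y1 and the plant control miR159a gave no Ct in any well.

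**Figure D3:**
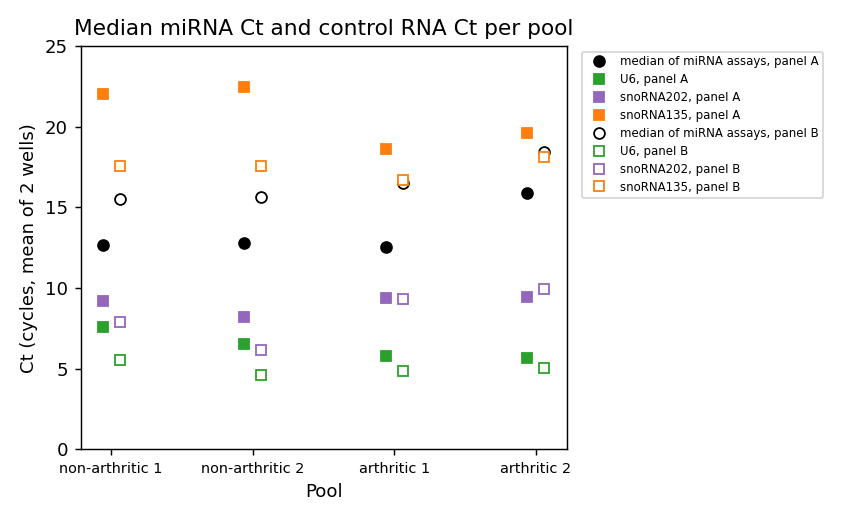
Ct in cycles (mean of 2 wells) of U6, snoRNA202 and snoRNA135 and the median Ct of the miRNA assays detected in all 4 pools, for each pool, with filled symbols for panel A and open symbols for panel B. In arthritic pool 2 the miRNA median of panel A is 15.9 against 12.5 in arthritic pool 1, while U6 on panel A is 5.67 against 5.78.

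The authors' deposited table gives log2 differences between the groups for 168 miRNA entries, of which 52 are higher and 68 lower by 2-fold or more in the arthritic pools. Across the 155 assays that the authors' deposited table and the 209 tested share with neither group at 0 there, Pearson's r was 0.969 and Spearman's rho 0.972, and 92.9% had the same sign. These are across assays, which are not independent replicates. miR-203 differed most, at -3.64 in the authors' deposited table and 0.87 here.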

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

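The median per chip, the Ct limits of 24 and 26, undetected values at the highest Ct, the control assays in the moderation and the well left out on chip A3 were chosen after seeing the data. Of the 45 changed miRNAs, 20 higher and 25 lower, the count was 25 (12 higher, 13 lower) with the panel mean, 50 (3 and 47) with U6, snoRNA135 and snoRNA202, 55 (1 and 54) with U6 alone, 58 (4 and 54) with the 2 snoRNAs, 40 with the median over both panels, 48 with quantile normalization, 34 with the median per chip and 8 (0 and 8) with raw Ct. The control-RNA references moved all changes down because of the control levels measured relative to the panel median. On panels A and B, U6 was higher in the arthritic pools by 2.86 and 1.97 log2 units and snoRNA135 by 4.61 and 2.03. snoRNA202 had differences of 0.76 and -0.77. Which reference is nearer the truth cannot be told from these values. For the other normalizations the cause was not tested. 5 of the 45, all lower, passed in the same direction under all 8. Under all but raw Ct 11 did, 10 of them lower and 1, miR-296-5p, higher. Both wells kept with the pool as a random block gave 83 (38 and 45). The 69 assays with concordant duplicates gave 10 (3 and 7). These 69 held 11 of the 45, of which 10 passed. The rest of the 45 had duplicate wells over 1 cycle apart in at least 1 pool. No moderation gave 0 (0 and 0; limma gave 92 and ordinary models 55 at an unadjusted p under 0.05). An adjusted p of 0.1 gave 79 (39 and 40), and an unadjusted p under 0.05 gave 92 (47 and 45), both by a looser threshold. The authors' deposited table at 2-fold gave 120 (52 and 68), with other values, other entries and no test, and the cause was not tested. Undetected values at the Ct limit of 35 gave 40, 9 of them higher and 13 of them among the 45, with the miR-17-92 list passing as 1 list, and at the highest Ct 37, 11 of them higher. Ct limits of 24 and 26 each left 16 lower. Control assays in the moderation gave 42. Leaving out the second listed well of arthritic pool 2 on chip A3 gave 45, of which 37 were the same miRNAs, losing miR-138, miR-142-3p, miR-19a, miR-136, miR-1982.2, miR-99b*, miR-1949 and miR-29a*. None of these 8 is on chip A3, and without the well the first 4 had log2 changes of -3.63, 3.56, 4.71 and -4.97 against -3.36, 3.83, 4.98 and -4.70, those of the last 4 were unchanged, and the adjusted p values were 0.0520 to 0.0796. Ct limits of 28, 32 and 40 changed nothing because no Ct lay above 26.997, so that they are void as tests, and single technical replicates were not run because wells are not numbered. Without 1 pool the count ranged from 0 to 121 (0 to 65 higher, 0 to 56 lower) and the lists passing from 0 to 1: it was 0 without non-arthritic pool 1 or 2, 121 without arthritic pool 1 and 97, with 1 list, without arthritic pool 2, each lone pool being assumed to vary like the other group. The deviations of same-numbered pools correlated at 0.074, which gave no sign of a pairing by number but cannot exclude one. A replicate block gave 66 changed miRNAs, 32 of them higher and 34 lower. The correlation with the authors' deposited table, 0.969, was 0.955 with the mean, 0.903 with the 3 control RNAs, 0.942 with U6 alone, 0.879 with the 2 snoRNAs, 0.949 with quantile normalization and 0.922 with the median per chip, and it was higher, 0.974, with the median over both panels and with raw Ct, where the interquartile range of the differences was 0.252 against 0.527. The 4 miRNAs detected only in the arthritic pools were 2 at a Ct limit of 24.

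Values that changed sign were as follows, as log2 changes. With U6, snoRNA135 and snoRNA202 they were miR-221 -0.49, miR-223 -0.98, miR-203 -1.87, miR-181a -0.32, miR-455 -0.81, miR-192 -2.52, miR-29c -1.94, let-7e -0.96, let-7i -1.02, miR-30b -1.86, miR-214 -0.42 and miR-10a -0.39, and the medians of the inflammation-responsive (-0.55), miR-29 (-1.94), let-7 (-2.02), miR-17-92 (-0.47), miR-30 (-2.45), Dlk1-Dio3 (-0.90), fibroblast (-2.16) and bone (-1.26) lists. With U6 alone they were miR-221 -0.60, miR-223 -1.09, miR-203 -1.98, miR-181a -0.43, miR-455 -0.93, miR-192 -2.63, miR-29c -2.05, let-7e -1.08, let-7i -1.13, miR-30b -1.97, miR-214 -0.54, miR-10a -0.51 and miR-199b -0.29, and the medians of the same lists in that order -1.44, -2.05, -2.14, -0.58, -2.56, -1.02, -2.55 and -1.38. With the 2 snoRNAs they were miR-221 -0.43, miR-223 -0.92, miR-203 -1.81, miR-181a -0.26, miR-455 -0.76, miR-192 -2.46, miR-29c -1.88, let-7e -0.91, let-7i -0.96, miR-30b -1.81, miR-214 -0.37 and miR-10a -0.34, and the list medians -0.43, -1.88, -1.97, -0.41, -2.39, -0.85, -1.90 and -1.21. With raw Ct they were miR-203 -0.62, miR-192 -1.27, miR-29c -0.69, miR-30b -0.61 and miR-199b -0.19, and the medians of the inflammation-responsive (-0.62), miR-29 (-0.69), let-7 (-0.77), miR-30 (-1.20), fibroblast (-1.19) and bone (-0.015) lists. The miR-30 median was -0.075 with quantile normalization and from -0.13 (without non-arthritic pool 1) to 0.68 without 1 pool, the miR-15/16 median 0.22 at a Ct limit of 24 and 0.14 with both wells detected, and the Dlk1-Dio3 median -0.94 with undetected values at the Ct limit. miR-451 was 0.072 with the median per chip and ranged without 1 pool from -1.53 to 0.54 (without arthritic pool 2), miR-192 -0.049 and miR-30d 0.021 without the well on chip A3, miR-205 and the epithelial median each ranged without 1 pool from -1.69 to 0.14 (without arthritic pool 1), and the adipose median from -1.39 to 0.35 (without non-arthritic pool 2). Without 1 pool these moved by over 1.5 times with no change of sign: miR-203 ran from 0.58 to 1.60, miR-192 from 0.054 to 0.74, miR-29c from 0.35 to 1.38, let-7i from 1.38 to 2.64, miR-30d from -1.99 to -0.98 and miR-30b from 0.69 to 1.47, and the medians of the inflammation-responsive list from 0.58 to 1.32, the lymphoid list from -1.90 to -0.84, the miR-29 family from 0.35 to 1.38, the miR-15/16 family from -1.31 to -0.84 and the Dlk1-Dio3 cluster from 1.13 to 2.11. None of these miRNAs or lists had passed the test, and the cause was not tested beyond the shift of the reference.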

Other observations

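All of the tests in this part were chosen only after the values they rest on had been seen in part, and the miRNAs of the first paragraph were named after their values were seen. The bounds first set against less muscle and dilution were met, but once the values had been seen they were judged too weak to exclude these explanations, which are therefore left open.

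Both strands of 25 miRNA precursors measured in all 4 pools could be paired by name, 19 of them by assays on different panels. The difference between the log2 changes of the strands passed for 3. miR-339-5p and miR-339-3p, of which the latter fell, had log2 changes of 1.21 and -6.26, a difference of 7.47 ± 0.72 (SE, limma adjusted p = 0.00816). miR-29b rose and miR-29b* fell, with log2 changes of 2.90 ± 0.77 and -3.54 ± 0.77, a difference of 6.44 ± 0.98 (SE, limma adjusted p = 0.0263). miR-16 and miR-16* had log2 changes of -6.43 and -2.03, a difference of -4.40 ± 0.86 (SE, limma adjusted p = 0.0475). miR-16 was read on chip A3, and this pair was not fitted again without the second listed well there. The other 22 pairs did not pass, and 13 of the 25 had opposite signs. Among the 22, miR-99b and miR-99b* differed by 7.75 ± 1.86, miR-30a and miR-30a-3p by 7.32 ± 1.86 and the strands of miR-671 by 5.73 ± 1.48 (SE, limma adjusted p = 0.0566 for each), while miR-126-5p and miR-126-3p had log2 changes of -2.02 and -2.38, and miR-140 and the human-named assay of miR-140-3p had log2 changes of -1.78 and -1.75, the latter 0.78 with the median per chip. Further falls were those of miR-196b, at -4.27 ± 0.80, miR-574-3p, at -4.72 ± 1.03 (from -5.95 to -2.91 without 1 pool), and miR-23b, at -3.33 ± 0.74.

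miRNAs encoded within 10 kb of each other, which are often processed from a shared transcript, changed by different amounts. miR-221 and miR-222 differed by 10.3 ± 0.75 log2 units and miR-15b and miR-16 by 9.68 ± 1.60 (SE, limma adjusted p = 0.00422 and 0.0222). Of 57 neighbour pairs 17 passed, or 27 without the second listed well on chip A3, where limma's prior had 66.3 degrees of freedom against 2.53. Without that well the 2 differences were 11.3 and 8.66. The pairs share members and are not independent. miR-16 lies next to both miR-15a and miR-15b, and its assay does not tell these places apart. Differences between chips and their normalization are argued against by the 23 pairs measured on 1 chip, where any constant per pool, panel or chip cancels. Their median absolute difference was 3.09 (lower quartile 1.78), and 3.07 without that well, and 10 of the 23 passed. The residual SD of the fit was 1.19. It is that of single assays, and a difference between 2 assays has a larger error unless they vary together. Assays that misread their target cannot be told apart from processing that differs between neighbours. The 8 pairs of assays with 1 miRNA name differed by a median of 1.43 against 2.55 for neighbours (one-sided permutation p = 0.13). Pairs with a rat-named assay, of miR-224, miR-146b and miR-409-3p, differed by 4.51, 2.47 and 1.73, and the others by at most 2.06. Of the 27 miRNAs in the passing neighbour pairs 0 had a repeat assay. A biological difference in how neighbours are processed or degraded in arthritic synovium stays open and untested.

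Arthritic pool 2 came up later than arthritic pool 1, by a median of 2.83 cycles on panel A and 2.34 on panel B. Less RNA in its reactions is argued against by U6, whose mean delay was 0.045 ± 0.22 cycles (SE from wells) against miRNA medians of 2.35 and 2.34 on the 2 chips that hold it, while the 46 miRNA assays under a Ct of 10 in arthritic pool 1 had a median delay of 2.29. Failure of a few chips as the whole cause is argued against too, since 7 of the 8 chips had a median delay of 1 cycle or more, but the chip medians ran from 0.81 to 4.13, so that a part from the chips stays open. A smaller share of miRNA in that pool's RNA, from isolation or from the tissue, stays open, and snoRNA135 was delayed by 1.22 cycles and snoRNA202 by 0.33. No biological explanation was tested, since both pools belong to 1 group.

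The lower muscle miRNAs may reflect the tissue dissected as well as the joint. Less muscle in the arthritic dissections would lower all muscle miRNAs alike if they are spread alike over the muscle dissected, which was not tested. The log2 changes of miR-133a and miR-206 differed by 4.66 ± 1.17 (SE, with miR-206 itself from -2.99 to -1.48 without 1 pool), or by 3.33 ± 1.18 without the second listed well on chip A3. Repeat assays differed by up to 4.51, for a mouse- and a rat-named assay of miR-224, and by at most 2.06 where neither was rat-named. With few repeat assays and only 2 muscle miRNAs measured in all 4 pools, less muscle cannot be excluded. Dilution of resident tissue by infiltrating cells would lower other resident markers as much, and the median change of miR-140, miR-455, miR-126-3p, miR-143 and miR-145 was -2.09 (from -4.12 to 1.93) against -4.74 for the muscle miRNAs, a gap of 2.64 that was 1.71 without that well, while the fibroblast list had a median of 0.31 that ran from 0.053 to 1.32 without 1 pool and was below 0 with the control-RNA references and raw Ct. Neither can be told apart from a change of these miRNAs within cells, because the RNA came from whole tissue, in which all cells are read together. The design's own difference, arthritis at day 10 against day 0, stays open as well.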
